A study of Mus musculus with 6 samples.

How the data were processed

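Affymetrix mouse 3' expression arrays were hybridised with biotin-labelled RNA of 6 thymic lymphomas, 1 array per tumour, 3 from Notch1+/+ and 3 from Notch1f/f mice. Per the labels, the tumour cells were collected after mechanical disruption of the tissue, without a sorting step, and total RNA was extracted with DNase treatment. The values deposited by the authors are MAS5 signal intensities per probe set on a linear scale, per the submitters' processing notes, which give no version. MAS5 combines the probes of a probe set into 1 signal after background correction. In the deposited table the mean of the middle 96% of values, with 2% trimmed at each end, was 100 on every array, so each array had been scaled to this target. Detection calls were not used here, so the signal of dim probe sets cannot be told from background by a call. Each column belongs to 1 tumour, and no column was left unused.

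Gene symbols came from an annotation table of the array and were matched through Entrez identifiers to a RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols. Of the 45101 probe sets, 64 were controls, 34945 had 1 symbol, 932 had several and 9160 had none in the table used. Of those with 1 symbol, 34741 matched the gene table, which also gave the chromosome and the order of genes, and 204 did not match it. Probe sets with several symbols or none were tested and counted but not named. List members with no named probe set are not analysed here.

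Intensities were put on the log2 scale after adding 16. Control probe sets were left out, as were probe sets whose mean log2 value lay under the 40th percentile of all probe sets (4.56, an intensity of 7.60), which left 27022. The groups were compared with lmFit and eBayes (trend = TRUE) in limma 3.58.1 under R 4.3.3, with Notch1f/f minus Notch1+/+ as the contrast, two-sided, and Benjamini-Hochberg adjustment. The prior degrees of freedom were 5.21. The labels give no batch, sex or pairing of the tumours, so no covariate was used, and age could not be separated from genotype. The median log2 difference over all tested probe sets was -0.04.

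Gene lists and chromosomes were tested with camera (preset correlation between genes 0.01, trend.var = TRUE) on 12043 genes, each represented by the probe set with the highest mean. The preset was compared with a correlation estimated from the arrays and, for the lists, with fry, which tests whether the genes of a list move one way on balance. A total of 30 lists was fixed before the data were examined, covering Notch targets and pathway, the Ikaros family and NuRD, thymocyte stages and mature T cells, T cell receptor signalling, leukaemia transcription factors, Myc and ribosome biogenesis, the cell cycle and its inhibitors, p53, apoptosis, cytokine, NF-kB and interferon genes, migration receptors, glycolysis and hypoxia, immediate-early and heat shock genes, sex-linked genes, and markers of B cells, macrophages, neutrophils, dendritic, erythroid, thymic epithelial, fibroblast, endothelial, NK and adipocyte cells. The sex-linked genes served as a check of samples, and 1 list with fewer than 3 measured genes was not tested. Members of a list were also counted with the adjustment over the list alone.

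The genes named were set by a rule fixed before the data were examined. It takes up to 12 genes per direction past the threshold with groups that do not overlap. Where fewer than 10 pass, it fills up to 10 per direction with the smallest p-values among genes with at least a 2-fold difference and no overlap. It adds a fixed set of Notch, thymocyte and tumour suppressor genes, and the up to 4 members of each list with the smallest p-values. Fos, Jun, Cd74 and H2-Aa values of single tumours are given to show a tumour that stood apart, and Fos and Jun were chosen after their values were seen.

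The fit was tested on simulated arrays with the observed means, in which 200 of 27022 probe sets were changed. The noise was independent between probe sets, while probe sets of real tumours can vary together. The shares of true and false calls given next therefore hold for independent noise only. With spreads drawn from the fitted prior, 18.0% of changes of 1 on the log2 scale, 90.0% of changes of 2 and 100% of changes of 3 were called, and 6 of 160 calls were false. With each probe set's own moderated spread, 22 of 185 calls were false. Alternatives fixed beforehand were a pseudocount of 1 or 64, no filter, a filter at the 60th percentile, quantile normalisation, median centring, eBayes without trend, array weights, each array left out, a threshold of 0.10, a linear model without moderation, the mean of a gene's probe sets, and the other set tests. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.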

Results

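Gene expression was measured in 6 primary thymic lymphomas of Ikaros-deficient mice, 1 microarray per tumour. All 6 mice were homozygous for the hypomorphic IkL allele of Ikzf1, the gene of the lymphoid transcription factor Ikaros, and carried a CD4-Cre transgene, which is active in developing thymocytes. In 3 mice, aged 18 to 20 weeks, both Notch1 alleles were wild type (Notch1+/+). In the other 3 mice, aged 8 to 10 weeks, both alleles were floxed (Notch1f/f), so that Cre could delete part of the gene. The tumours came from separate mice, and age and genotype changed together, so no comparison here separates them. Each array gave an intensity for 45101 probe sets, of which 64 were controls. Between 23.1% and 25.0% of probe sets had an intensity over 100. Across the tested probe sets, Pearson's r between pairs of arrays ranged from 0.918 to 0.962. The first principal component held 39.3% of the variance and had the 3 Notch1+/+ tumours at one end and Notch1f/f tumours 1 and 3 at the other. Notch1f/f tumour 2 lay between them, and its array correlated with the Notch1+/+ arrays at 0.955 to 0.961. The number of arrays, 3 per group, limits the precision of every value below.

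The sex-linked genes served as a check of the samples. Eif2s3y, a Y-linked gene, had an intensity of 526 in Notch1+/+ tumour 1, 814 in Notch1f/f tumour 1 and 584 in Notch1f/f tumour 2, and of at most 1.5 in the other 3 tumours. Xist, the RNA of the inactive X chromosome, reached 4307 in Notch1+/+ tumour 2 and 4343 in Notch1f/f tumour 3. Notch1+/+ tumour 3 had an Xist intensity of 111 and an Eif2s3y intensity of 0.3, so that neither gene was high there. Both groups therefore held tumours with and without Y-linked expression.

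The comparison of the genotypes asks how lymphomas that arose in mice with floxed Notch1 differ from those with wild-type Notch1. The Notch1f/f tumours differed most clearly by very high Slc15a2, a proton-coupled oligopeptide transporter, and by a far lower signal of 1 probe set of Rpgrip1, a gene of the photoreceptor cilium. Slc15a2 had intensities of 477 to 885 in the 3 Notch1f/f tumours and of 0.3 to 2.7 in the Notch1+/+ tumours. Its log2 difference was 5.28 ± 0.28 (SE), with an adjusted p of 1.37e-04 in limma, and 8.14 and 3.47 with a pseudocount of 1 and 64 in place of 16. This Rpgrip1 probe set had intensities of 1673 to 2185 in the Notch1+/+ tumours and of 47.2 to 49.2 in the Notch1f/f tumours, a log2 difference of -4.86 ± 0.20 (adjusted p = 3.10e-05), while the 3 other Rpgrip1 probe sets reached at most 49.9 on any array of either group. Tubb2b, a beta-tubulin isotype, was 6.57-fold higher in the Notch1f/f tumours, at 1387 ± 141 (SD, n = 3) against 202 ± 58.2 (limma adjusted p = 0.00918). Saa3, an acute-phase serum amyloid, was 5.94-fold lower, at 23.9 ± 9.36 against 221 ± 57.3 (limma adjusted p = 0.0373). Ppp1r3e, a glycogen-targeting phosphatase subunit, was lower, with intensities of 1.1 to 2.1 against 50.9 to 60.1 (adjusted p = 0.0109) and a log2 difference of -2.03, or of -4.45 and -0.87 with a pseudocount of 1 and 64. The folds of genes are on the scale of log2(intensity + 16), which understates the change of dim genes.

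These 5 probe sets, 2 higher and 3 lower, were the only ones of 27022 past an adjusted p of 0.05 in limma. An adjusted p of 0.10 was passed by 40 probe sets, 23 higher and 17 lower in the Notch1f/f tumours. An unadjusted p of 0.05 was passed by 3659, where chance gives 1351 on average. The 2 groups did not overlap in 18.6% of probe sets, and chance gives 10% on average. Of these, 315 were at least 2-fold higher and 300 at least 2-fold lower. Probe sets that vary together across tumours can exceed such averages in any 1 split. These counts were not made for other splits of the tumours, so the excess alone does not show an effect of genotype. The count past 0.05 depended on single tumours. It was 14 without Notch1+/+ tumour 3, 12 without Notch1f/f tumour 2, 3 without Notch1f/f tumour 1 and 2 without Notch1f/f tumour 3. Slc15a2 and Rpgrip1 passed with each tumour left out in turn. Saa3 lost its call whichever tumour was left out (adjusted p from 0.0504 to 0.292) with a pseudocount of 1 or 64 (0.0601 and 0.0568) and with quantile normalisation (0.0676). Tubb2b lost it without Notch1f/f tumour 1 (0.108) or 3 (0.0685), and Ppp1r3e without any 1 of the 3 Notch1f/f tumours (0.0607 to 0.126). With no filter on dim probe sets, Saa3 and Ppp1r3e both lost it (0.0880), and with array weights the count was 27.

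The genes next in rank did not pass the threshold, with limma adjusted p-values from 0.0693 to 0.0981, although their groups did not overlap and differed by at least 2-fold. On the side of higher values in the Notch1f/f tumours, Ms4a4b, a membrane protein of T cells, had 326 ± 140 against 24.1 ± 15.1. Tubb2a, the isotype encoded beside Tubb2b, had 1334 ± 230 against 303 ± 109, from a probe set type that can detect more than 1 transcript. Btg1, an antiproliferative gene, had 4382 ± 528 against 2155 ± 256, and Ypel3, a growth suppressor, 466 ± 175 against 89.5 ± 18.6. Lama3, a laminin chain, had 118 ± 60.2 against 3.47 ± 2.63. The other 3 genes on this side were Xkrx, Bambi-ps1, an annotated pseudogene, and Dnajc17. On the side of lower values, Slc7a1, a transporter of cationic amino acids, had 196 ± 50.5 against 690.5 ± 188. Coro2a, a coronin, had 90.6 ± 42.6 against 396 ± 49.6, and Rif1, a regulator of replication timing, 18.8 ± 8.80 against 146 ± 29.7. Tbx21, which encodes the T-bet transcription factor, had 3.53 ± 2.25 against 40.7 ± 11.7. Vegfa, Inhbb and Gm26782 were the remaining 3 on this side. Rpgrip1, Ppp1r3e and Gm26782 all lie on chromosome 14.

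**Figure D1:**
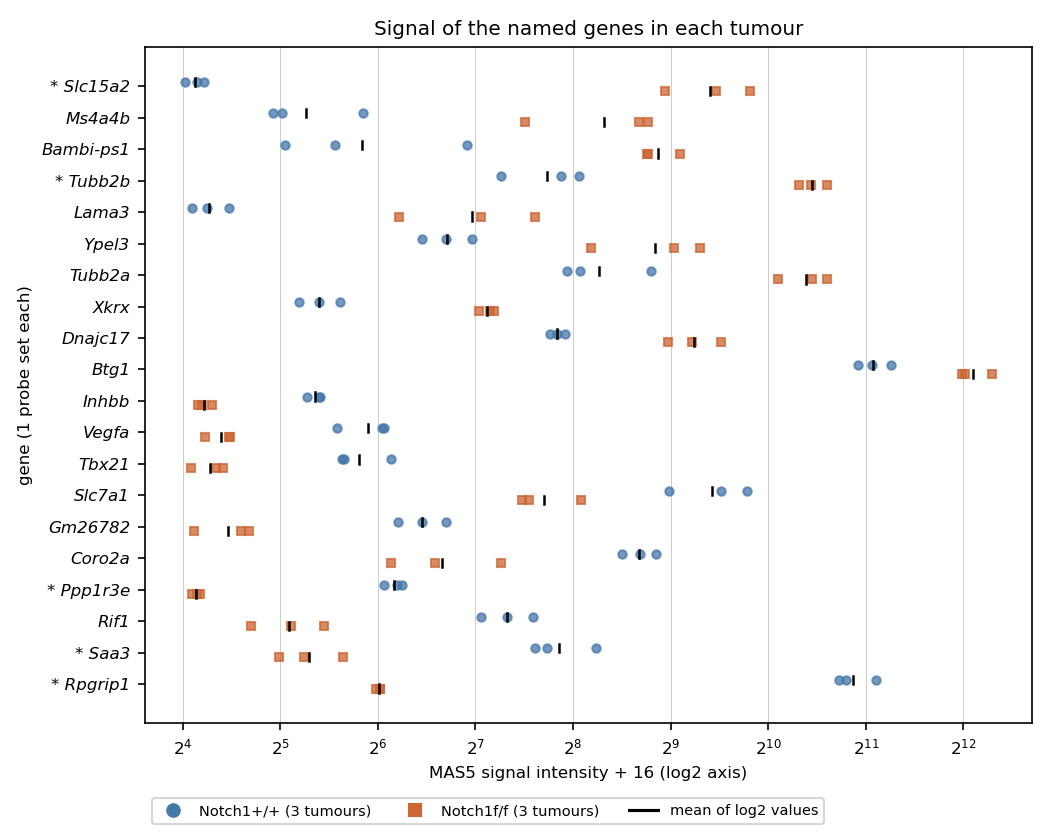
MAS5 signal intensity plus 16, on a log2 axis, of 1 probe set for each of the 20 leading genes, with circles for the 3 Notch1+/+ tumours, squares for the 3 Notch1f/f tumours, bars at the means of the log2 values and an asterisk for the 5 genes past an adjusted p of 0.05. Before 16 was added, Slc15a2 had intensities of 477 to 885 in the Notch1f/f tumours and of 0.3 to 2.7 in the others, and Rpgrip1 of 47.2 to 49.2 against 1673 to 2185.

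The floxed gene itself was detected in all 6 tumours. Notch1 was read by a pair of probe sets that differed. On the dimmer one it had 1861 ± 456 (SD, n = 3) in the Notch1f/f tumours and 1005 ± 683 in the Notch1+/+ tumours, a log2 difference of 1.04 ± 0.40 (limma adjusted p = 0.319, exact permutation p = 0.2). On the brighter one it had 3252 ± 192 against 3002 ± 570, a log2 difference of 0.13 ± 0.16 (limma adjusted p = 0.752, exact permutation p = 0.5). The exact two-sided test cannot go below 0.1 with 3 tumours against 3. The floxed alleles were designed to lose promoter and exon 1 sequence of Notch1, while the array reads the 3' part of transcripts. The positions of these probe sets were not looked up, so their signal does not check the deletion or the genotype labels. The Ikzf1 probe sets differed in direction, at a log2 difference of 0.37 ± 0.28 for the brighter and -0.79 ± 0.35 for the dimmer (each limma adjusted p = 0.582 and 0.365).

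Genes that Notch signalling activates did not shift as a group. Of 15 measured Notch target genes, 8 had a log2 difference above 0 and 7 below, with a mean of 0.01, a median of 0.25 and a camera adjusted p of 0.677. None of the 15 passed limma, adjusted over the list alone or over all probe sets. An unadjusted p under 0.05 was found for 7 of them, and for 3659 of all 27022 probe sets. Without overlap between the groups, 4 of the 15 were higher and 1 was lower, where 18.6% of all probe sets did not overlap. Members moved both ways, so a mean near 0 does not show that no Notch target changed. Dtx1, a Notch-induced ubiquitin ligase, had 3919 ± 478 in the Notch1f/f tumours against 2795 ± 373 (log2 difference 0.49 ± 0.16, limma adjusted p = 0.295). Hes1, a Notch-induced repressor, had 463 ± 315 against 163 ± 77.8, and Notch3 had 1227 ± 285 against 820 ± 169. Nrarp, a feedback inhibitor of Notch, had 312 ± 245 against 989 ± 1129, where Notch1+/+ tumour 3 alone reached 2290. Ptcra, the pre-T cell receptor alpha chain, had 762 ± 311 against 997 ± 403, and Myc 649 ± 269 against 882 ± 280. Il2ra had 966 ± 549 against 941 ± 828. Skp2 and Shq1 had log2 differences of -1.02 ± 0.33 and -0.66 ± 0.27. The list mean rested on single tumours, at -0.25 without Notch1+/+ tumour 1 (camera adjusted p = 0.601) and 0.35 without Notch1+/+ tumour 3 (0.0193). The 23 measured components of the Notch pathway were higher in the Notch1f/f tumours in camera, by a mean log2 difference of 0.19 (adjusted p = 0.0446, and adjusted p = 0.348 with an estimated correlation). Only Lfng, a glycosyltransferase that modifies Notch receptors, passed adjusted over the list alone, at 40.2 ± 14.1 against 8.37 ± 5.93. The list's call was lost without Notch1+/+ tumour 1 (adjusted p = 0.0729) or 3 (0.138), without Notch1f/f tumour 1 (0.0593) or 2 (0.0890), with the 60th percentile filter (0.165), with array weights (0.0635) and with the mean of a gene's probe sets (0.142, with a list mean of 0.12).

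Across the 28 gene lists tested, camera called 13, of which 9 were higher and 4 lower in the Notch1f/f tumours. No list passed in camera when the correlation between its genes was estimated from the arrays, where 3 had an unadjusted p under 0.05, and none passed with fry, where 7 did. No gene of any list passed over all probe sets in limma, so counts of members below are adjusted over the list alone.

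Genes of mature T cells were higher in the Notch1f/f tumours. Of 15 measured, 14 had a log2 difference above 0, 9 rose adjusted over the list alone and none fell, with a mean of 1.08 (camera adjusted p = 4.13e-09, and adjusted p = 0.293 with an estimated correlation). Besides Ms4a4b, they included Ccr7, a chemokine receptor for lymph node homing, at 70.2 ± 20.5 against 6.13 ± 9.33. S1pr1, a receptor for thymic exit, had 62.9 ± 12.2 against 16.9 ± 10.6, and Gimap3, a GTPase of T cell survival, 51.7 ± 5.49 against 17.5 ± 6.11. The 17 measured T cell receptor signalling genes were higher by a mean of 0.32 in camera (adjusted p = 0.00266, and adjusted p = 0.293 with an estimated correlation), with 14 above 0, none past limma singly and 3 at an unadjusted p under 0.05. Among them, Plcg1 had 1025 ± 278 against 558 ± 57.0, Lcp2 798 ± 122 against 515 ± 47.2, Cd3e 2167 ± 620 against 1437 ± 182 and Cd3d 4898 ± 851 against 3687 ± 810. The 15 cytokine receptor and JAK-STAT genes were higher by a mean of 0.36 (camera adjusted p = 0.00266, and adjusted p = 0.293 with an estimated correlation, and by 0.20 with the mean of a gene's probe sets), again with none past limma singly and 4 at an unadjusted p under 0.05. Pim1, a cytokine-induced kinase, had 286 ± 75.6 against 163 ± 12.3, and Bcl6, Il4ra and Jak1 also had groups that did not overlap. The control probe sets for 18S ribosomal RNA were higher on all 3 Notch1f/f arrays too, for example at 285 ± 34.7 against 97.8 ± 30.5 for the 3' probe set.

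The lists of earlier thymocyte stages did not move as groups. The 15 double-positive thymocyte genes had a mean log2 difference of -0.09 and a median of 0.02. Camera, which compares the test statistics of a list with those of the other genes, placed them on the higher side (adjusted p = 0.677). Arpp21 was the member that fell, at 422 ± 140 against 987 ± 126 (limma p adjusted over the list alone, 0.00988). Rag2 had 92.3 ± 83.8 against 270 ± 175, Rag1 2334 ± 458 against 2537 ± 417, and Bcl2l1, a survival gene, 285 ± 32.2 against 170 ± 41.8. The probe sets of Cd8a disagreed, with log2 differences from -0.43 ± 0.31 to 0.73 ± 0.24, and so did those of Cd4, at -0.68 ± 0.37 and 0.02 ± 0.45. None of these passed. The 12 immature thymocyte genes had a mean of 0.01 and a median of -0.08 (camera adjusted p = 0.926), with Dntt at 2525 ± 929 against 1561 ± 625. The 17 transcription factors of T cell leukaemia had a mean of 0.04 and a median of -0.05 (0.907), with Myb at 3105 ± 401 against 3938 ± 243. The 14 genes of the Ikaros family and the NuRD chromatin complex had a mean of 0.04 (0.778), and Hdac2 had 654.5 ± 126 against 1098 ± 99.0. No gene of these last 3 lists passed limma over the list alone, and 1, 1 and 3 had an unadjusted p under 0.05.

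Genes of cell division and of growth were lower in the Notch1f/f tumours. Of 27 measured cell cycle genes, 26 had a log2 difference below 0, with a mean of -0.46 (camera adjusted p = 1.70e-07, and adjusted p = 0.368 with an estimated correlation), although none passed limma singly and 11 had an unadjusted p under 0.05. Tyms, which makes thymidylate, had 56.3 ± 6.17 against 127 ± 14.3, Kif11, a spindle motor, 259 ± 38.6 against 440 ± 31.2, and Mcm3, part of the replicative helicase, 1097 ± 432 against 1869 ± 80.7. Of 24 measured Myc targets and ribosome biogenesis genes, 22 were below 0, with a mean of -0.50 (camera adjusted p = 7.20e-07, and adjusted p = 0.457 with an estimated correlation). Of these, 4 fell adjusted over the list alone and 20 did not pass. They were Rrs1, at 580 ± 177 against 1095 ± 55.7, Polr1b, a subunit of the polymerase that makes ribosomal RNA, at 140 ± 62.6 against 284 ± 5.35, Gnl3 and the mitochondrial chaperone Hspd1. On both lists Notch1f/f tumour 2 lay nearest the Notch1+/+ tumours. Its mean log2 level of the Myc list was 9.97, against 9.39 and 9.51 in Notch1f/f tumours 1 and 3. The Notch1+/+ tumours had 10.02 to 10.20. The Myc list's mean difference was -0.38 without Notch1f/f tumour 1 and -0.67 without Notch1f/f tumour 2. The cell cycle list's was -0.37 and -0.59, with each call kept. The 16 glycolysis and hypoxia genes were lower, with a mean of -0.36 (camera adjusted p = 0.00519, and adjusted p = 0.348 with an estimated correlation). Of these, 3 fell over the list alone, namely Vegfa, at 5.17 ± 2.05 against 44.2 ± 10.7, Pfkl, a phosphofructokinase, at 149 ± 66.6 against 406.5 ± 37.9, and the oxygen sensor Egln3, at 423 ± 16.02 against 682 ± 120. The control probe sets for 18S ribosomal RNA, which belong to no list, were higher, at 217 ± 18.5 against 59.1 ± 32.6 for the 5' probe set. A difference in labelling or hybridisation between the groups was not tested, so this signal is not read as ribosome production.

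Among the 14 cell cycle inhibitors and tumour suppressors, Cdkn1b, the inhibitor p27, rose adjusted over the list alone, at 1072 ± 284 against 353 ± 66.0, and Cdkn2b fell, at 4.57 ± 2.42 against 18.5 ± 2.74. Cdkn2a, which lies beside Cdkn2b, had 13.7 ± 9.20 against 37.8 ± 18.3 (limma adjusted p = 0.305). The list as a whole had a mean and a median of -0.08, with camera on the higher side (adjusted p = 0.926). The 15 p53 target genes had a mean of 0.30 (camera adjusted p = 0.177) and the 15 apoptosis regulators 0.11 (0.501), with none past limma over the list alone in either and 1 and 3 at an unadjusted p under 0.05. Bbc3, a pro-apoptotic gene, had 230 ± 169 against 63.9 ± 51.2, and Mcl1, a survival gene, 1644 ± 79.6 against 1178 ± 72.8. The p53 list mean rested on single tumours, at 0.53 without Notch1+/+ tumour 2, where it passed camera (adjusted p = 0.00631), and at 0.08 without Notch1+/+ tumour 1 (0.996) and 0.19 without Notch1f/f tumour 3 (0.214). The 11 NF-kB target genes had a mean of 0.17 (0.547), where Notch1f/f tumour 3 alone had a high Tnfaip3 intensity of 1358.

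Markers of macrophages, dendritic cells and B cells and genes of the interferon response were also higher in the Notch1f/f tumours, while fibroblast markers were lower. Of 13 macrophage and monocyte markers, 8 rose adjusted over the list alone and none fell, with a mean log2 difference of 1.01 (camera adjusted p = 1.94e-05, and adjusted p = 0.457 with an estimated correlation). Mpeg1 had 212 ± 75.5 against 70.0 ± 31.6, the protease Ctss 626 ± 116 against 186 ± 120, and the complement genes C1qb and C1qc 329 ± 126 and 221 ± 53.6 against 95.6 ± 66.9 and 71.4 ± 47.9. Notch1+/+ tumour 1 had the lowest level of this list, whose mean difference was 0.61 without it (adjusted p = 0.00130), and no member exceeded 500 on every array. The 8 dendritic cell markers were all above 0, with a mean of 1.16 (camera adjusted p = 8.00e-04, and adjusted p = 0.457 with an estimated correlation) with none past limma singly and 4 at an unadjusted p under 0.05. Their class II genes were highest in Notch1f/f tumour 3, where Cd74 reached 1830 and H2-Aa 1223, against 248 and 312 in Notch1f/f tumour 1, and without tumour 3 the list mean was 0.62 (adjusted p = 0.00453). B cells and macrophages also express these genes. The 6 B cell markers were higher by 0.62 (camera adjusted p = 0.0195, and adjusted p = 0.457 with an estimated correlation), with Cd79b and Ighm past over the list alone, and lost the call without Notch1+/+ tumour 1 (0.0928), without Notch1f/f tumour 3 (0.0855, with a mean of 0.33) and with array weights (0.135, with a mean of 0.41). The 13 interferon response genes were higher by 0.40 (camera adjusted p = 6.28e-04, and adjusted p = 0.348 with an estimated correlation). Of these, 4 rose over the list alone, namely Rtp4, at 229 ± 77.1 against 58.8 ± 28.7, Rsad2, Irf7 and Xaf1. Without Notch1+/+ tumour 3 the list mean was 0.23 (adjusted p = 0.0193).

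The 10 fibroblast markers had 9 members below 0 and a mean of -0.72 (camera adjusted p = 0.00469, and adjusted p = 0.457 with an estimated correlation). Mgp, a matrix protein, fell over the list alone, at 3.07 ± 3.51 against 28.3 ± 11.4. The collagen gene Col1a2 reached 978 in Notch1+/+ tumour 2 and 53.3 in Notch1+/+ tumour 3, and the call was lost without tumour 2, at a list mean of -0.26 (adjusted p = 0.325), and with the 60th percentile filter (0.132). The 16 immediate-early and heat shock genes had a mean of 0.68 (camera adjusted p = 0.0189, and adjusted p = 0.559 with an estimated correlation), with Zfp36 higher and the chaperone Hsph1 lower over the list alone. This list stood apart in Notch1f/f tumour 3, where Fos reached 1505 and Jun 799. Without that tumour its mean was 0.18 (adjusted p = 0.294), and its adjusted p was 0.102 without Notch1+/+ tumour 1, 0.132 with the 60th percentile filter and 0.111 with array weights. The 13 migration and homing receptors had a mean of 0.44 (camera adjusted p = 0.0646), with Ccr7, S1pr1 and the integrin Itga4 higher and Ccr4 lower over the list alone. It passed without Notch1+/+ tumour 2 (0.00545) or Notch1f/f tumour 1 (0.0361). The 7 neutrophil markers had a mean of -0.32 (0.0608), with Camp lower over the list alone, at 6.73 ± 4.89 against 22.3 ± 4.30. It passed without Notch1+/+ tumour 3 (0.0193) or Notch1f/f tumour 1 (0.0264) and with no filter on dim probe sets (0.0175). No shift was called for the 4 erythroid markers (mean -0.08, camera adjusted p = 0.907), the 5 thymic epithelial markers (0.06, with camera on the lower side, 0.998), the 3 endothelial markers (-0.04, 0.930) or the 5 markers of NK and cytotoxic cells (-0.08, 0.944). In the last list Tbx21 was lower and Gzma higher over the list alone. A single adipocyte marker was measured, Fabp4, at 108 ± 12.7 against 58.3 ± 67.1, too few for a list test.

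**Figure D2:**
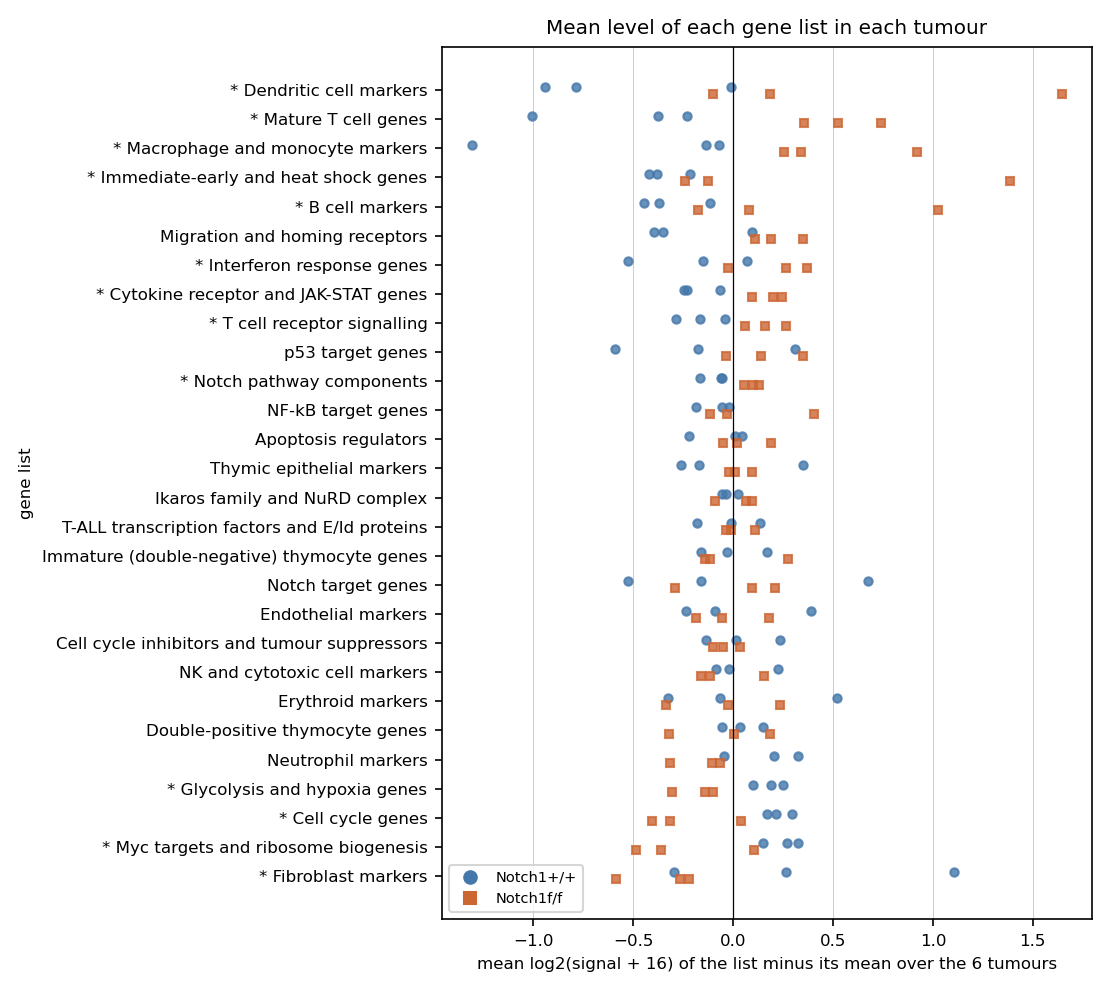
Mean log2(intensity + 16) of each of the 28 tested gene lists in each tumour, minus its mean over the 6 tumours, with circles for Notch1+/+, squares for Notch1f/f and an asterisk for the 13 lists past a camera adjusted p of 0.05. Mature T cell genes and cell cycle genes differ by means of 1.08 and -0.46, while immediate-early and dendritic cell genes are highest in a single Notch1f/f tumour.

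Genes were also grouped by chromosome, since thymic lymphomas can gain or lose whole chromosomes. Of 20 chromosomes, camera called 3, with lower expression of chromosomes 14 and 15 and higher expression of chromosome X in the Notch1f/f tumours. The 477 genes of chromosome 15 had a mean log2 difference of -0.19 (adjusted p = 3.61e-04), the 415 of chromosome 14 a mean of -0.15 (0.00970) and the 353 of chromosome X a mean of 0.14 (0.00970). None of the 3 passed with an estimated correlation (adjusted p = 0.718 for each), and none of the 20 chromosomes had an unadjusted p under 0.05 in that camera test. The shifts were not shared by all tumours of a group. Chromosome 15 had a median deviation from the mean of the 6 tumours of 0.20 in both Notch1+/+ tumours 2 and 3, and of -0.10 in Notch1+/+ tumour 1. In Notch1+/+ tumour 1, chromosomes 1, 5, 11 and 14 deviated by 0.22, 0.22, 0.17 and 0.19 and chromosome X by -0.22. Without Notch1+/+ tumour 1, or with no filter on dim probe sets, only chromosome 15 was called, and without Notch1+/+ tumour 2 the count rose to 7.

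**Figure D3:**
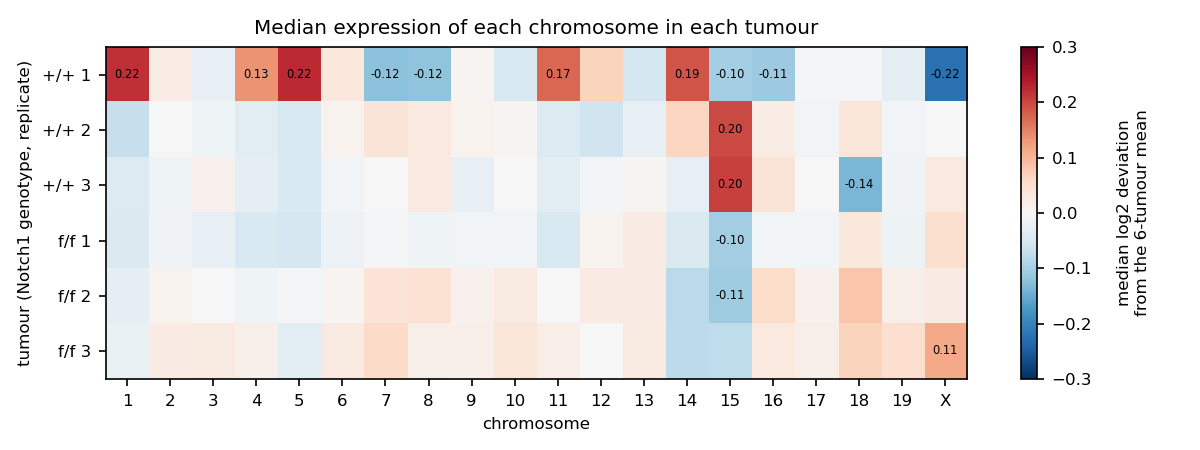
Median log2 deviation of the genes of each chromosome from the mean of the 6 tumours, coloured from blue to red over -0.3 to 0.3, with tumours in rows and chromosomes in columns; deviations of at least 0.1 in size are printed. Chromosome 15 stands at 0.20 in Notch1+/+ tumours 2 and 3, and chromosomes 1 and 5 both at 0.22 in Notch1+/+ tumour 1.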

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

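The tests of chance position, of a probe variant and of a lower share of tumour cells, and the choice of the 3 patterns weighed here, came after the results were seen. The control probe sets for 18S ribosomal RNA, which enter no comparison, were higher on all 3 Notch1f/f arrays. Their intensities were 285 ± 34.7 against 97.8 ± 30.5 for the 3' probe set, 217 ± 18.5 against 59.1 ± 32.6 for the 5' probe set and 247 ± 90.8 against 95.1 ± 45.1 for the middle one, ratios of mean intensities of 2.92, 3.67 and 2.59. The exact permutation p was 0.1 for each, the smallest that 3 against 3 allows. The actin 3'/5' ratio, a measure of RNA integrity, did not separate the groups (1.52 ± 0.15 against 1.66 ± 0.50, exact permutation p = 0.8), and its highest value, 2.23, was that of Notch1+/+ tumour 1. The labels give no batches, so a difference in labelling or hybridisation between the groups was not tested.

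The first pattern is that Rpgrip1, Ppp1r3e and Gm26782, 3 of the 16 lower genes with an adjusted p under 0.10, lie within 5 Mb on chromosome 14. Placing the 16 genes at random gave as many in 1 window in a share of 0.0198 of 10000 draws, but the genes were seen to lie together before the window was set, so chance position stays open. A loss of the DNA of the whole region between them in the Notch1f/f tumours would lower its other genes, but the 24 neighbours with an intensity over 100 in the Notch1+/+ tumours had a median log2 difference of -0.0565 ± 0.107 (SE), so that is argued against. Of the 24, 5 lay below -0.6, or 20.8% against 8.60% of such genes elsewhere, and 2 above 0.6. These 5, chosen after their values were seen, were Osgep, Pnp, Sall2, Prmt5 and Haus4, and smaller losses within the region stay open. For Ppp1r3e the other probe set was also lower, by -1.17, which goes against a sequence variant under a single probe set. That probe set was dim, however, at 26.6 to 37 against 2.7 to 6.1. It fell short of the mean intensity of 100 in the Notch1+/+ tumours that was asked of the Rpgrip1 probe sets. A variant therefore stays open for Ppp1r3e, and also for Rpgrip1, which had 0 other probe sets bright enough to compare. Of its 3 others, 1 was lower without overlap, at 21 to 49.9 against 11.4 to 16.7 (log2 difference -0.68, unadjusted p = 0.0400 in limma), and the other 2 stayed under 10 on every array. A strain difference on chromosome 14 between the mice, age and genotype remain open and were not tested.

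The second pattern is that mature T cell and macrophage genes were higher while growth genes were lower. A lower share of tumour cells, with all other cells raised evenly, would raise the markers of macrophages and fibroblasts alike. The macrophage list's log2 difference exceeded the fibroblast list's by 1.73 ± 0.30 (SE). With each array left out and the same probe sets kept, it did so by 1.57 to 1.96. With the filter and the choice of probe sets redone each time, the range was 1.49 to 1.93. These values argue against such an even rise only. A lower share of tumour cells through more macrophages or other immune cells stays open, since it need not raise fibroblast markers. None of the 13 macrophage or 10 fibroblast markers is on another of the fixed lists, and 1 fibroblast marker exceeded 500 on every array. Targets of FOXO factors, which act when growth signalling is low, were picked as a further list after the pattern was seen. Their own values had not been looked at. Of 18, 16 were above 0 (mean 0.57, unadjusted p of 0.0313 in limma's fry), as higher FOXO activity would give. Only 4 were higher without overlap and 1 was lower, where 18.6% of all probe sets did not overlap. Amino acid response genes, picked in the same way, were below 0 for 28 of 29, as a weaker amino acid response would give. Their mean was -0.58 (unadjusted p of 0.0283 in fry), with 14 lower without overlap. Both lists were read on the arrays that showed the pattern, so neither is independent support for a cause. Both adjusted p-values over the 3 lists picked were 0.0470 in fry, and an exact permutation of list means could not go below 0.1. In camera with an estimated correlation the unadjusted p-values were 0.0473 for FOXO targets and 0.0680 for amino acid response genes, both 0.102 adjusted over the 3 lists, so neither passed there. Other regulators of growth, age and genotype remain open.

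The third pattern is the chromosome-wide shifts of single tumours. A gain of chromosome 15 in Notch1+/+ tumours 2 and 3 would raise the whole chromosome, and the lowest median deviation of any of 4 equal parts of its genes in these tumours was 0.131, consistent with a gain along its length. Scaling of genes by their level is argued against, since in these tumours genes of other chromosomes matched on expression deviated by -0.0077 and -0.0135. For the 5 shifted chromosomes of Notch1+/+ tumour 1, a test added later gave matched genes a deviation of at most 0.0196 in the direction of the shift, which argues against scaling there too. Of 6 upward shifts of at least 0.15 in single tumours, 5 exceeded 0.1 in all 4 parts of the chromosome, and the 1 downward shift of that size, of chromosome X in Notch1+/+ tumour 1, was under -0.1 in all 4. These counts use the median of a whole chromosome and miss shifts of a part. In Notch1+/+ tumour 2, the 4 parts of chromosome 12 in order had 0.087, 0.12, -0.32 and -0.21. In Notch1+/+ tumour 3, 1 part of chromosome 18 had -0.39. Copy number itself was not measured.

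Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 5 probe sets past the threshold, and 2 of the 10 gave as many, the highest other giving 10. For the gene lists the real count of 13 was reached by 1 split, the real one, with 12 as the highest other. For the chromosomes 6 splits reached the real count of 3, with 9 as the highest other.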

How the results depend on the processing

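Every alternative described here was fixed before the data were examined. No paired analysis was possible because the tumours came from separate mice and the labels give no replicate numbers; the tumour numbers used in the text only follow the order of the samples. The cause of the changes below was not tested, except that fewer tumours were compared where one was left out. Dim signals, with no detection calls used, and 3 arrays per group limit what can be called.

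The 5 probe sets past the threshold became 3 with no filter on dim probe sets, 11 with median centring, 27 with array weights, 40 at an adjusted p of 0.10, 3 in the linear model without moderation and 2 to 14 with each tumour left out. They were 4 with either other pseudocount, the 60th percentile filter or quantile normalisation, and 5 without the trend. All 5 were among those called with median centring and with array weights. The 13 lists became 0 with an estimated correlation and 0 with fry, and 9 to 14 under the other alternatives. The 3 chromosomes became 1 with no filter, 1 with array weights, 0 with an estimated correlation and 1 to 7 with each tumour left out. The Notch target genes, with a mean log2 difference of 0.01, had -0.00479 with a pseudocount of 1, -0.0500 with the mean of a gene's probe sets and -0.25 to 0.35 with each tumour left out. Over these alternatives the 13 called lists gave 220 values and the 5 called probe sets 69. None of them changed direction, while 42 and 16 no longer passed. Among the other lists and named probe sets, 7 and 23 values passed. The 60th percentile filter left too few genes for a value of the B cell, erythroid, thymic epithelial, endothelial and NK lists and removed 32 of the named probe sets, and the filter removed 2 with a pseudocount of 1, 2 without Notch1+/+ tumour 2 and 3 without Notch1f/f tumour 3. With a pseudocount of 64 the interferon, Notch pathway and fibroblast means moved to 0.22, 0.12 and -0.44, with a pseudocount of 1 the fibroblast mean was -1.09, and with no filter the B cell mean was 0.41, with each call kept.

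Changes of direction occurred in lists and genes that did not pass in the main test. The direction of a list is the sign of its mean log2 difference, a definition taken up after a first run had used camera's own direction, under which 37 values of the lists that were not called changed direction, against 36 by the mean, and no called list did under either. With a pseudocount of 1, the erythroid list had a mean of 0.0478. With a pseudocount of 64, the immature list had -0.00347, the cell cycle inhibitors 0.00748, the endothelial list 0.0271, the NK list 0.0470 and Cd4 -0.00476. With no filter the endothelial list had 0.00929 and the NK list 9.21e-04. With the 60th percentile filter the immature list had -0.12 and the inhibitors 0.14. The endothelial list had 0.0123 with quantile normalisation and 0.00405 with median centring, and 1 Cd8a probe set had -0.00368 with quantile normalisation. With array weights, Cd8a probe sets had -0.11 and -0.15, Alas2 -0.23, the immature list -0.0427 and the leukaemia factors -3.29e-05. The Ikaros and NuRD list had -0.0536 with the mean of a gene's probe sets.

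With each tumour left out, the means ranged from -0.11 to 0.13 for the immature list, -0.0537 to 0.12 for the leukaemia factors, -0.18 to 0.0126 for NK markers, -0.16 to 0.0214 for cell cycle inhibitors, -0.35 to 0.25 for erythroid, -0.0603 to 0.25 for thymic epithelial and -0.14 to 0.14 for endothelial markers, -0.20 to 0.0507 for double-positive genes and -0.0180 to 0.27 for NF-kB targets. The log2 difference ranged from -0.50 to 0.95 and from -0.45 to 0.85 for the Il2ra probe sets, from -0.39 to 0.21, -0.18 to 0.26 and -0.16 to 0.25 for 3 Cd8a probe sets, from -0.20 to 0.32 for the dimmer Dtx1 probe set, from -0.53 to 0.35 for the brighter Cd4 probe set, from -0.23 to 0.48 for Alas2, -0.21 to 0.0810 for Egfl7, -0.0835 to 0.0828 for Epcam, -0.0511 to 0.13 for Klf1, -0.25 to 0.0520 for Krt8, -0.61 to 0.39 for Nkg7 and -0.37 to 0.24 for Slc4a1.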

Other observations

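A test chosen before its result was seen looked at the genes around Notch1. If DNA inherited with the floxed Notch1 allele from another strain changed the expression of nearby genes, differences would gather there. Of 203 genes within 10 Mb of Notch1, 3 had an unadjusted p under 0.01, which is 1.48%, against 399 of 11840 elsewhere, 3.37% (odds ratio 0.43, 95% interval 0.0876 to 1.28, Fisher's exact p = 0.167). The interval's upper end lies under the value of 1.5 set beforehand, so these data argue against a broad effect of this kind around Notch1.

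Genes of sterol synthesis, a further list picked after the main results, had a mean log2 difference of -0.52 in the Notch1f/f tumours, with 12 of 16 below 0 (unadjusted p of 0.0589 in limma's fry and 0.141 in camera with an estimated correlation). Sqle, a rate-limiting enzyme of the pathway, had a log2 difference of -1.48 ± 0.39 and Cyp51 of -1.31 ± 0.30, while Insig1, a feedback regulator, had 0.22 ± 0.28. Among the FOXO targets, Txnip had a log2 difference of 1.48 ± 0.48 and Sesn3 of 1.19 ± 0.37. In both, Notch1f/f tumour 2 lay within the range of the Notch1+/+ tumours. Its intensity was 593.9 against 377.7 to 754.4 for Txnip and 195.7 against 99.9 to 202.9 for Sesn3. Among the amino acid response genes, Mthfd2, a mitochondrial folate enzyme, had -1.44 ± 0.40 and Psat1, of serine synthesis, -1.04 ± 0.28. None of these 7 genes passed the adjustment over all probe sets in limma, with adjusted p-values from 0.202 to 0.749.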
